A study of Homo sapiens with 60 samples.

How the data were processed

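The series measured messenger RNA by RNA sequencing in HT29, a human colorectal adenocarcinoma cell line, after 24 h with herbal extracts or vehicle. Per the labels' protocols, at least RNA integrity number 7 was required, libraries were made from 1 µg of total RNA with the MGIEasy directional (strand-marking) kit, and read pairs of 100 bp were sequenced on the MGIseq system. Per the submitters' processing notes, the tools included FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, with the genome build GRCh38 (hg38). The annotation version and the counting settings are not given in the sources used here. Reads that fit several near-identical genes were shared between them by RSEM, so values of the AKR1C genes, the metallothioneins, the UGT1A genes, RN7SL1 and RN7SL2, the CXCL chemokines, GUSBP11 and NPIPB4 are less certain than those of single-copy genes, as is RTEL1-TNFRSF6B, a read-through transcript that overlaps both of its parent genes.

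The deposited table holds estimated counts (RSEM expected counts) per gene for the whole series, made by the authors with no normalization that the values show. It has 60675 genes and 270 columns. Of these columns, 60 matched the labels of samples described here by name and 210 were not used. Before rounding, 8.68% of the values were not whole. All were rounded to whole numbers for the count tests. No line of the table (0) named anything other than a gene. Symbols came from a gene name table that held 56558 of the identifiers, and coordinates from GENCODE release 29 on GRCh38, which held 57055. Total counts ran from 10.35 to 40.05 M per library with a median of 23.83 M.

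Groups came from the sample labels. Vehicle and 6 extracts at 3 doses each formed 19 groups of 3 libraries (57 libraries). Bojungikgi-tang had 1 library per dose, so it entered no test. The sample labels name 0.1% DMSO as vehicle and the series' design text 2%. That text also says that a lower top dose was used where the concentration inhibiting growth by 20% lay under 500 µg/mL, whereas the labels give 500 µg/mL for every high dose used here. Ethanol extracts, the wortmannin control and samples excluded for low RNA, all mentioned in the design text, are not analysed here.

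Genes were filtered with filterByExpr by group, which left 16485, and scaled with TMM in edgeR 4.0.16 (R 4.3.3). A quasi-likelihood model of group means was fitted to all 57 libraries at once, so that the groups shared the estimate of spread. The biological coefficient of variation was 8%. The 27 comparisons were each extract and dose against vehicle (18), high against low dose (6 extracts), and 3 pairs of extracts at the high dose that shared a library set. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. CPM are counts per M on TMM-scaled totals. Errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of its F statistic. They are less certain for genes of low counts. Errors of CPM are standard deviations over 3 libraries.

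Of 34 gene lists fixed before the data were examined, 29 had at least 5 tested genes. They cover receptor and stress pathways, metabolism, cell cycle, inflammation, cell states of the intestinal epithelium, and measures of RNA quality. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over all lists and the 6 extracts together. The markers of other cell types fell below 5 tested genes each and are given as levels. Genes named in the text were chosen by a rule fixed before the data were examined: per extract at the high dose, the 8 largest rises and 8 largest falls among genes past the threshold with mean log2 CPM of at least 1, all 3 treated libraries beyond all 3 vehicle libraries, and a symbol that is not a clone or non-coding antisense name. The same rule with 5 and 5 served the other comparisons, and up to 4 members with the smallest adjusted p were named from each list described. CYP1A1, CYP1B1, HMOX1 and NQO1 could be named throughout. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

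For Bojungikgi-tang, log2 ratios of CPM + 1 to the vehicle mean were taken, genes with a mean of at least 5 CPM were described, and the median of each list was placed among 10000 random lists matched on mean expression. Correlations of fold changes between extracts were set beside 20 simulations of unchanged groups against shared, simulated vehicle libraries. All counts there, those of vehicle included, were drawn from the vehicle means, the fitted spread and the real library sizes. Replicate numbers of the labels were checked for pairing by the correlation of deviations from the group means. They were taken to pair the libraries only where every r passed a lower bound. That held in 1 comparison, bupleurum high against low dose (r = 0.25, 0.22 and 0.19), where a replicate block gave 50 genes against 48 without it. In citrus peel high against low (r = 0.33, 0.06 and 0.25) each high-dose library still correlated best with the low-dose library of its own number. The same held for Yijung-tang low against vehicle (r = 0.19, 0.03 and 0.17). Weaker pairing is therefore not excluded there. Chi-square per degree of freedom between replicates lay between 2.11 and 66.3, which is more than counting noise and does not tell separate cultures from separate library preparations.

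The tests were tested on simulated data. With counts drawn for citrus peel at the high dose against vehicle, 16485 genes and 200 changed genes, edgeR recovered 97% of those changed by a fold of 1.5, 95.5% at 2 and 100% at 4, with 11 false among 206 calls. The changed genes all had mean log2 CPM of at least 1. The drawn counts hold the fitted spread but no difference between sets or batches and no deviating library. Recovery and false calls in the real data may therefore be worse. Alternatives tried were DESeq2 1.42.0, median-ratio (RLE) scaling, no filter on low counts, a fit of the compared groups alone, a replicate block, and each library left out in turn. After the data were seen, 4 more were added: a term for library batch, libraries of matched batch (set 5 without replicate 3), 4 deviating libraries left out, and mitochondrially encoded genes left out.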

Results

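RNA-seq counts were analysed from HT29, a human colorectal adenocarcinoma cell line, collected 24 h after exposure to hot-water extracts used in Korean herbal medicine. The single-herb extracts were Citri Unshius Pericarpium (dried citrus peel, called citrus peel), Cimicifugae Rhizoma (cimicifuga), Bupleuri Radix (bupleurum root) and Aconiti Lateralis Radix Preparata (processed aconite root). The formulas, each a mixture of herbs, were Yijung-tang, Banhasasim-tang and Bojungikgi-tang. Every extract was given at 500, 100 and 20 µg/mL, called high, medium and low dose. The series asks which transcripts respond to each extract and how the response changes with dose. Vehicle (0.1% DMSO per the sample labels, 2% per the design text) and 6 of the 7 extracts had 3 libraries per group, 57 libraries in 19 groups, whereas Bojungikgi-tang had 1 library per dose. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

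Total counts per library, ran from 10.35 to 40.05 M, with a median of 23.83 M, and 16485 genes were tested. The sample descriptions carry codes whose first part is read here as a library set, a term the labels do not use. The titles of all samples name the same batch, BatchB. Vehicle forms set B1 (18.26 to 31.81 M counts), citrus peel and cimicifuga set 5 (14.92 to 40.05 M), bupleurum and aconite set 6 (15.94 to 35.67 M), Yijung-tang and Banhasasim-tang set 7 (10.35 to 24.48 M) and Bojungikgi-tang set 8 (12.75 to 18.26 M). Each comparison with vehicle is therefore also a comparison between sets, while high against low dose, and extracts of the same set against each other, are not.

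With all groups in the fit, aconite changed far more genes than any other extract (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05): 1396 rose and 1184 fell at the high dose, of which 330 changed at least by 1 on the log2 scale. At the same dose bupleurum changed 244 genes, cimicifuga 211, Banhasasim-tang 196, Yijung-tang 182 and citrus peel 5. The counts followed dose for aconite (2580, 740 and 261 from high to low) and cimicifuga (211, 1 and 0). From high to low the counts were 182, 264 and 241 for Yijung-tang and 196, 478 and 473 for Banhasasim-tang. These orders did not hold without single libraries. Without vehicle 1 the counts were 61, 13 and 18 for Yijung-tang and 95, 95 and 93 for Banhasasim-tang, and without 1 library of the group itself the medium and low doses gave as few as 33 and 23 for Yijung-tang and 163 and 138 for Banhasasim-tang. In the fit of aconite at the high dose, leaving out any single library left between 1792 and 2968 genes. With only the compared groups in the fit the order at the high dose turned, with 181 genes for aconite and 238 for bupleurum. The fit of all groups shares its estimate of spread between groups. Chi-square per degree of freedom between replicates reached 66.3 in aconite high and 53.4 in Banhasasim-tang high, against 6.44 in bupleurum high. Standard errors and p-values of the shared fit may be too small for groups whose libraries differ more. Across the fits of all groups, single libraries moved most other counts by more than 1.5 times, with values beside each extract.

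**Figure D1:**
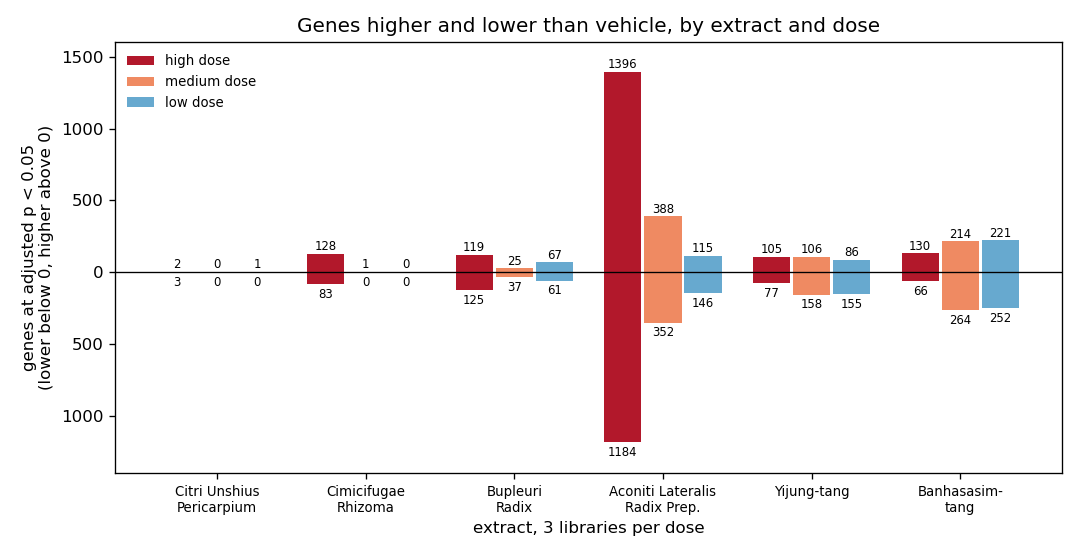
Number of genes higher than vehicle (above 0) and lower (below 0) at an adjusted p under 0.05, for each of 6 extracts at the high, medium and low dose, 3 libraries per group. Aconite at the high dose had 1396 higher and 1184 lower genes, the most of any group.

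Libraries also differed in ways the groups do not give. RN7SL2, the RNA of the signal recognition particle (ENSG00000274012, chromosome 14, 49862550 to 49862849, minus strand), lay between 3.5 and 9.82 CPM in 15 libraries, namely vehicle and replicates 1 and 2 of set 5. It lay between 40.08 and 228.43 CPM in the other 42, namely replicate 3 of set 5 and all of sets 6 and 7. Within set 5, 1494 genes differed between these batches in edgeR, 825 higher and 669 lower where RN7SL2 was high. The labels do not name these batches. Only in set 5 do libraries of the same group lie on both sides, so a term for this batch is estimated there alone. It cannot part batch from set for sets 6 and 7 against vehicle. Separately, 4 libraries, each the farthest from the mean of its own group, were examined and left out together in an alternative fit chosen after the data were seen. Banhasasim-tang high 3 (0.228), aconite high 1 (0.215) and high 3 (0.189) and Banhasasim-tang high 1 (0.179) deviated by more than vehicle 1 and were kept, the first 2 of these also by more than bupleurum medium 2. Aconite high 2 (root mean square deviation 0.362 on the log2 scale), Banhasasim-tang high 2 (0.345) and vehicle 1 (0.169) had short transcripts high, with rank correlations of deviation and exon length of -0.44, -0.59 and -0.51. Their ribosomal protein mRNAs lay above their group means by medians of 0.48, 0.40 and 0.22. Bupleurum medium 2 (0.204) deviated the other way, with a correlation of 0.31 and a ribosomal protein median of -0.12.

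**Figure D2:**
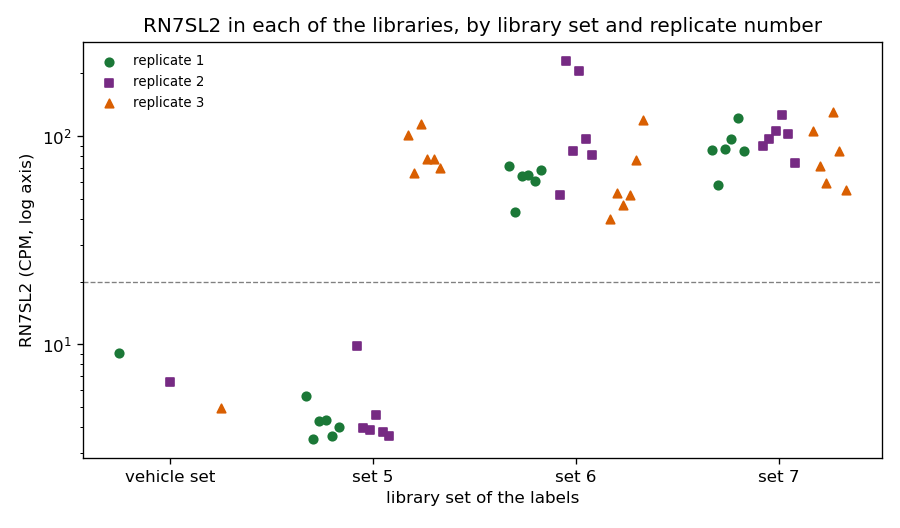
CPM of RN7SL2 (log axis) in each of the 57 libraries, by library set (first part of the sample code) and replicate number of the labels, with a dashed line at 20 CPM. In set 5, replicate 3 lies above the line with sets 6 and 7, and replicates 1 and 2 lie below it with vehicle.

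Citrus peel gave few calls against vehicle in the fit of all libraries. At the high dose 5 genes passed edgeR's test, against 142 without replicate 2 of every group, 0 without replicate 1 or 3 of every group and 353 without a filter on low counts. LY6G5B rose by 0.58 ± 0.11 and PAN2, a subunit of a deadenylase, by 0.48 ± 0.09 on the log2 scale (edgeR adjusted p = 0.00874 for both). ACSS2, which makes acetyl-CoA from acetate, fell by 0.45 ± 0.07 (edgeR adjusted p = 0.00279). The other calls, named after their values were seen, were IGFL2-AS1 (log2 fold change -0.77) and ENSG00000279573 (-1.45). LY6G5B, PAN2 and ENSG00000279573 were called in 15, 14 and 14 of the 18 comparisons with the shared vehicle libraries and in 0 of those of high with low dose in edgeR. ACSS2 was also the clearest dose effect, at 16.5 ± 0.392 CPM in high against 23.7 ± 1.59 in low (log2 fold change -0.53 ± 0.07, edgeR adjusted p = 4.65e-05). Among the 11 genes that differed between high and low dose, the ER chaperone HSPA5 rose by 0.26 ± 0.05 and IRF9, a subunit of the interferon-responsive factor ISGF3, fell by 0.56 ± 0.12. The medium dose gave 0 calls in edgeR (224 without replicate 2 of every group, 0 without replicate 1 or 3, 496 without a filter), with 1584 genes at an unadjusted p under 0.05 and 9 calls in DESeq2, and the low dose 1, NHERF4 (0.69, edgeR adjusted p = 0.0356), chosen after its value was seen. Leaving out 1 library ended the calls of LY6G5B 0.277 (vehicle 1 or 2, high 1 or 3), PAN2 0.161 (vehicle 1 or 2, high 1 or 2) and ACSS2 0.0527 (vehicle 2), each with its highest edgeR adjusted p (high against vehicle). Calls lost without single libraries, with the highest edgeR adjusted p, were those of IRF9 0.38 (low 2 or 3, high 1, 2 or 3) and HSPA5 0.279 (low 1, 2 or 3, high 1 or 2) (high against low).

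Small coordinated shifts were visible in lists, the cytosolic ribosomal proteins, a measure of RNA quality, among them. Against vehicle they lay lower in citrus peel (camera adjusted p = 6.53e-11), cimicifuga (3.61e-10), bupleurum (2.33e-06) and Yijung-tang (0.00281), with 0 of 40 past edgeR's test in each. None of these held with an estimated correlation (adjusted p = 0.396, 0.402, 0.539 and 0.7 with an estimated correlation in camera), and vehicle 1 itself had these mRNAs above its group mean by a median of 0.22. Of 24 SREBP2 targets of cholesterol synthesis and uptake, 0 passed over all genes and 10 were lower when adjusted over the list alone (camera adjusted p = 1.27e-11 and 0.00358 with an estimated correlation). INSIG1 had a log2 fold change of -0.27 ± 0.07. Of 8 aryl hydrocarbon receptor targets, genes of the sensor for planar aromatic compounds, 0 passed over all genes and 6 were higher adjusted over the list alone (camera adjusted p = 3.79e-06 and 0.00358 with an estimated correlation), with CYP1A1 at 1.32 ± 0.46 (edgeR adjusted p = 0.375) and CYP1B1 at 0.34 ± 0.09. None (0) of 25 TFEB targets of autophagy and lysosomes passed, 3 were lower adjusted over the list alone, and the list median was -0.07 (camera adjusted p = 0.000248 and 0.0115 with an estimated correlation). Against the low dose, 27 DNA replication genes had a median of 0.12 with 0 past the test over all genes and 8 adjusted over the list alone (camera adjusted p = 1.57e-18 and 0.000435 with an estimated correlation). The 23 interferon response genes had a median of -0.38 with 1 lower and 11 lower adjusted over the list alone (camera adjusted p = 1.67e-21 and 0.00406 with an estimated correlation). HMOX1 (0.12) and NQO1 (-0.03) did not pass. The high-dose count was 2 without vehicle 1, 0 without vehicle 2, 1 without citrus peel high 1 and 3 without high 2 or 3. The low-dose call was lost (0) without any 1 of its 6 libraries. The high-against-low count was 2, 3 and 6 without high 1, 2 and 3 and 4 and 2 without low 2 and 3. In DESeq2 the high dose gave 33 calls, and the compared groups alone gave 10 in edgeR, and 30 for high against low.

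Cimicifuga at the high dose raised detoxification and antioxidant genes. CYP1A1, an aryl hydrocarbon receptor target (ENSG00000140465, chromosome 15, 74719542 to 74725610, minus strand), rose by 2.89 ± 0.37 on the log2 scale, to 2.40 ± 0.599 CPM from 0.294 ± 0.158 in vehicle (edgeR adjusted p = 7.89e-07). The aldehyde dehydrogenase ALDH3A1 rose by 1.16 ± 0.08, the aldo-keto reductases AKR1C2, AKR1C1 and AKR1B10 by 1.15 ± 0.12, 1.01 ± 0.13 and 0.85 ± 0.09. HMOX1, which degrades heme (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), rose by 0.96 ± 0.09, to 18.2 ± 0.444 CPM from 9.37 ± 0.726 (edgeR adjusted p = 1.86e-10). DPH6, an enzyme of diphthamide synthesis, fell by 1.00 ± 0.11 (edgeR adjusted p = 5.57e-09). In all, 128 genes rose and 83 fell, 15 of them by at least 1 on the log2 scale. GUSBP11 (0.96) and CCDC78 (0.83, called in 11 of the 18 comparisons with the shared vehicle libraries) also rose, and DPYSL3 (-1.05), ADH1C (-0.95), SELENOH (-0.69), the urea transporter SLC14A1 (-0.67) and RASL11A (-0.66) fell. The calls of DPYSL3 0.0999 (high 2), ADH1C 0.0918 (vehicle 1 or 2, high 2) and SELENOH 0.494 (vehicle 1 or 2, high 1, 2 or 3) did not hold without the libraries in brackets, each given with its highest edgeR adjusted p (high against vehicle).

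Of 22 targets of NRF2, the antioxidant transcription factor, 18 rose, 0 fell and 4 did not pass, with 20 higher adjusted over the list alone (camera adjusted p = 9.12e-77 and 3.13e-12 with an estimated correlation). GCLC and GCLM, which together make glutamate-cysteine ligase for glutathione, rose by 0.58 ± 0.05 and 0.76 ± 0.07, and NQO1 by 0.48 ± 0.09. Of 8 aryl hydrocarbon receptor targets 6 rose, the same number adjusted over the list alone (camera adjusted p = 1.87e-33 and 1.88e-10 with an estimated correlation), with CYP1B1 at 0.73 ± 0.09 and UGT1A6 at 0.69 ± 0.09. Cholesterol export genes of LXR had 3 of 7 higher, 4 adjusted over the list alone (camera adjusted p = 3e-08 and 5.79e-05 with an estimated correlation), among them the exporters ABCG1 (0.83 ± 0.12) and ABCA1 (0.61 ± 0.14). Of 24 SREBP2 targets 1, INSIG1 (-0.25 ± 0.07), fell, 8 adjusted over the list alone (camera adjusted p = 1.55e-08 and 0.0145 with an estimated correlation). In the metallothionein list, zinc-binding proteins and metal response genes, MT1E (-0.76 ± 0.13) and MT2A (-0.75 ± 0.16) fell, and all 7 were lower adjusted over the list alone (camera adjusted p = 9.56e-11 and 7.91e-05 with an estimated correlation). Xenobiotic export and metabolism genes had 4 of 10 higher and 5 adjusted over the list alone (camera adjusted p = 7.04e-05 and 0.00784 with an estimated correlation), with the pump ABCC2 at 1.37 ± 0.25. ATF4 targets of the integrated stress response had 3 of 23 higher and 5 adjusted over the list alone (camera adjusted p = 5.12e-05 and 0.0247 with an estimated correlation), with the cystine importer SLC7A11 at 0.75 ± 0.09 and CHAC1 at 0.83 ± 0.16. NF-kB and chemokine genes had 0 of 16 past the test, 2 adjusted over the list alone and a median of 0.25 (camera adjusted p = 0.000184 and 0.00221 with an estimated correlation). Not every call held without 1 library: lost, with the highest edgeR adjusted p, were MT2A 0.115 (vehicle 1, high 1), ABCA1 0.112 (vehicle 1 or 2, high 2) and INSIG1 0.242 (vehicle 1, 2 or 3, high 2 or 3) (high against vehicle).

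Against the low dose of cimicifuga, which shares its library set, 67 genes rose and 77 fell. Leading rises were again CYP1A1 (2.10 ± 0.33), AKR1C2 (1.27 ± 0.12), ALDH3A1 (1.17 ± 0.08), AKR1C1 (1.10 ± 0.13) and HMOX1 (1.09 ± 0.09). Leading falls were ADH1C (-1.20 ± 0.20), DPYSL3 (-0.98 ± 0.23), DPH6 (-0.93 ± 0.11), NAALADL2 (-0.70 ± 0.12) and BCAS3 (-0.67 ± 0.11). NRF2 targets had 19 of 22 higher, 20 adjusted over the list alone (camera adjusted p = 3.78e-135 and 8.74e-16 with an estimated correlation). At the medium dose LY6G5B alone passed (0.63, edgeR adjusted p = 0.00767, chosen after its value was seen) and the low dose gave 0 calls in edgeR, with 1362 genes at an unadjusted p under 0.05 and 4 calls in DESeq2. High-dose counts were 116 and 112 without vehicle 1 and 2 and 114 and 122 without cimicifuga high 1 and 2. For the medium dose they were 0 without vehicle 1, vehicle 2 or medium 1, 4 without vehicle 3 and 3 without medium 2, and for the low dose 1 without low 1. For high against low they were 79 and 83 without high 1 and 2 and 78 and 72 without low 2 and 3. With the compared groups alone in the fit the high dose gave 107 genes and high against low 329. A term for the RN7SL2 batch gave 208 genes at the high dose, of which 178 were also called without it, and ended the call of INSIG1. Leaving out 1 library ended the calls of DPYSL3 0.229 (low 2 or 3, high 2), each with its highest edgeR adjusted p (high against low).

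Bupleurum at the high dose raised CYP1A1 to 3.86 ± 0.101 CPM from 0.294 ± 0.158 (log2 fold change 3.57 ± 0.34, edgeR adjusted p = 7.47e-10). CYP1B1, another cytochrome P450 under the same receptor, rose by 1.01 ± 0.09 and ALDH3A1 by 0.98 ± 0.08. The neutrophil chemokine CXCL1 rose by 0.80 ± 0.18 (edgeR adjusted p = 0.0098) and the Wnt antagonist DKK1 fell by 0.69 ± 0.11 (edgeR adjusted p = 5.59e-05). In all, 119 genes rose and 125 fell. CCDC78 (0.92), GUSBP11 (0.90), HR (0.82) and PGGHG (0.69) rose, CCDC78 and PGGHG being called in 11 and 12 of the 18 comparisons with the shared vehicle libraries. Falls were seen for 7SK (-2.67 ± 0.58), the small nuclear RNA that restrains P-TEFb, NAIP (-0.95), SELENOH (-0.76), SALL4 (-0.70), TMEM91 (-0.69), BDNF (-0.67) and SLC14A1 (-0.62). Aryl hydrocarbon receptor targets had 6 of 8 higher, also 6 adjusted over the list alone (camera adjusted p = 1.36e-41 and 9.17e-12 with an estimated correlation), including TIPARP (0.61 ± 0.07) and ALDH1A3 (0.55 ± 0.08). NRF2 targets had 10 of 22 higher, 16 adjusted over the list alone (camera adjusted p = 1.87e-23 and 5.41e-06 with an estimated correlation), including AKR1B10 (0.67 ± 0.09), GCLC (0.37 ± 0.05) and HMOX1 (0.34 ± 0.09), with NQO1 not passing (0.29). Of 16 NF-kB and chemokine genes CXCL1 and CXCL8 rose, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00845 and 0.0247 with an estimated correlation). Without 1 library some calls of high against vehicle were lost, here with the highest edgeR adjusted p and the libraries: 7SK 0.0577 (high 1 or 2), HR 0.118 (vehicle 1 or 2, high 1 or 2) and CXCL1 0.115 (vehicle 2 or 3, high 2). Also lost were SELENOH 0.274 (vehicle 1, high 1, 2 or 3), SALL4 0.145 (vehicle 2, high 3) and CXCL8 0.17 (vehicle 1, 2 or 3, high 1, 2 or 3). Further losses were TMEM91 0.182 (vehicle 1, high 2 or 3), BDNF 0.227 (vehicle 1, 2 or 3, high 1 or 2) and HMOX1 0.251 (vehicle 1, 2 or 3, high 1, 2 or 3).

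High against low dose of bupleurum changed 48 genes, 29 up and 19 down. CYP1A1 (2.90 ± 0.29), ALDH3A1 (0.92 ± 0.08), CXCL1 (0.85 ± 0.17), CYP1B1 (0.84 ± 0.09) and AKR1C2 (0.81 ± 0.12) rose, and REC8 (-0.74), the protease CTSO (-0.59), CD200 (-0.54) and the metalloreductase STEAP4 (-0.53) fell. NRF2 targets again had 10 of 22 higher, 17 adjusted over the list alone (camera adjusted p = 7.1e-64 and 2.93e-11 with an estimated correlation). Against vehicle the medium dose gave 25 higher and 37 lower genes and the low dose 67 and 61. Without vehicle 1 or 2 the counts from high to low dose were 98 or 137, 4 or 37 and 30 or 31; without vehicle 3 the medium and low doses gave 195 and 63. Without replicates 1, 2 and 3 of the extract they were 130, 106 and 99 at the high dose, 302, 22 and 119 at the medium dose and 67, 26 and 31 at the low dose. High against low gave 27 and 30 without high 1 and 2 and 23 without low 3. A term for the RN7SL2 batch, estimated within set 5 alone, gave 77, 20 and 14 genes in edgeR. Without the term 65, 9 and 11 of these were also called. At the high dose it ended the calls of HR, CXCL1, 7SK, SELENOH, SALL4, TMEM91, BDNF, HMOX1 and CXCL8. The compared groups alone gave 5 genes at the medium dose and 125 for high against low. The calls of CXCL1 0.162 (low 3, high 2), REC8 0.173 (low 2, high 1 or 3) and CD200 0.175 (low 3, high 1) did not hold without the libraries in brackets, each given with its highest edgeR adjusted p (high against low).

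Aconite at the high dose moved CYP1A1 more than any other named gene, to 102 ± 5.61 CPM from 0.294 ± 0.158 in vehicle, a log2 fold change of 8.29 ± 0.25 (edgeR adjusted p = 6.51e-29). At the medium dose the value was 8.16 ± 0.25 and at the low dose 3.60 ± 0.34. Chemokine and stress genes rose as well: CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242, plus strand) by 4.04 ± 0.15, CXCL8 by 3.07 ± 0.17 and CHAC1, a glutathione-degrading enzyme of the stress response, by 2.98 ± 0.15. CXCL8 stood at 24.6, 57.2 and 31 CPM in aconite high 1, 2 and 3 against 4.42 ± 0.623 in vehicle, highest in the deviating library high 2. Both mitochondrial ribosomal RNAs rose. MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601) rose by 4.56 ± 0.12, to 31400 ± 1760 CPM from 1330 ± 86.1. MT-RNR2 (ENSG00000210082, 1671 to 3229) rose by 3.27 ± 0.10, to 102000 ± 8860 CPM from 10600 ± 553. The mRNA of the complex I subunit MT-ND4 fell by 1.60 ± 0.17, to 3500 ± 944 CPM from 10600 ± 1090.

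**Figure D3:**
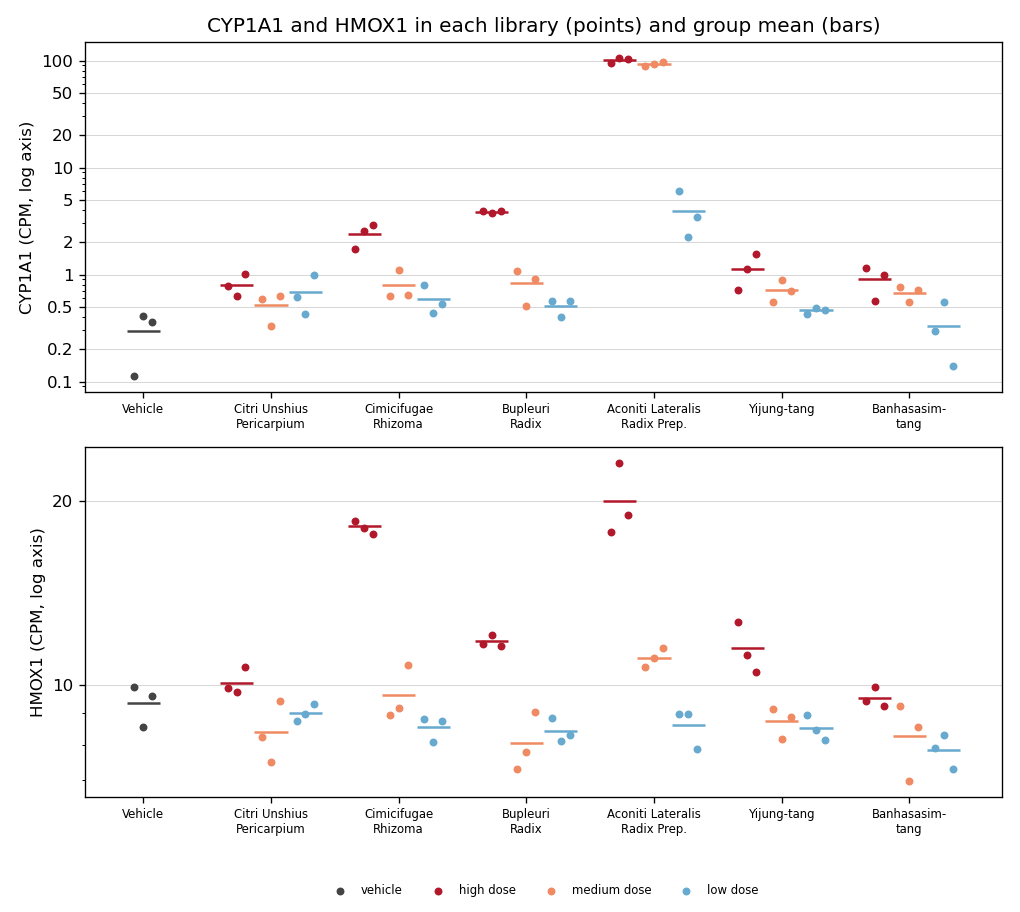
CPM (log axis) of CYP1A1 and HMOX1 in each library (points) with group means (bars) for vehicle and 6 extracts at the high, medium and low dose. CYP1A1 reached a mean of 102 CPM in aconite at the high dose against 0.294 in vehicle, and HMOX1 20 in aconite and 18.2 in cimicifuga at the high dose against 9.37.

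Among lists, 7 of 8 aryl hydrocarbon receptor targets rose, also 7 adjusted over the list alone (camera adjusted p = 1.11e-85 and 1.49e-16 with an estimated correlation), with CYP1B1 at 2.81 ± 0.10, ALDH1A3 at 1.99 ± 0.08 and ALDH3A1 at 1.82 ± 0.08. ATF4 targets had 20 of 23 higher, 21 adjusted over the list alone (camera adjusted p = 3.22e-85 and 1.02e-14 with an estimated correlation), with asparagine synthetase (ASNS) at 2.08 ± 0.09, the serine synthesis enzyme PSAT1 at 1.45 ± 0.06 and DDIT4, an inhibitor of mTORC1 signalling, at 1.83 ± 0.08. At the medium dose 2 and at the low dose 0 of these 23 passed. NRF2 targets had 20 of 22 higher, 21 adjusted over the list alone (camera adjusted p = 3.63e-53 and 2.07e-10 with an estimated correlation), with GCLC at 0.77 ± 0.05, SLC7A11 at 1.21 ± 0.09, HMOX1 at 1.09 ± 0.09 and NQO1 at 0.89 ± 0.09. NQO1 stood at 799, 1270 and 815 CPM in aconite high 1, 2 and 3 against 518 ± 29 in vehicle, highest in the deviating library high 2. NF-kB and chemokine genes had 14 of 16 higher, also 14 adjusted over the list alone (camera adjusted p = 2.82e-33 and 4.04e-14 with an estimated correlation), with CCL20 at 4.00 ± 0.32 and the adhesion molecule ICAM1 at 1.25 ± 0.10. Immediate early genes had 13 of 22 higher and 1 lower, 14 and 1 adjusted over the list alone (camera adjusted p = 3.46e-08 and 0.00358 with an estimated correlation), led by ATF3 (1.45 ± 0.15) and DUSP5 (0.98 ± 0.11). Hypoxia and glycolysis genes had 9 of 22 higher, 9 adjusted over the list alone (camera adjusted p = 0.000324 and 0.0104 with an estimated correlation), led by VEGFA (0.82 ± 0.07). Xenobiotic metabolism genes had 4 of 10 higher, 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000694 and 0.0241 with an estimated correlation), led by ALAS1 (0.87 ± 0.05).

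Mitochondrially encoded mRNAs had 11 of 13 lower and 2 not passing, 12 lower adjusted over the list alone (camera adjusted p = 1.99e-17 and 0.0173 with an estimated correlation), MT-CO3 at -1.24 ± 0.14 and MT-CO1 at -0.97 ± 0.11 among them. Goblet cell and mucin genes had 6 of 16 lower, 7 adjusted over the list alone (camera adjusted p = 0.0031 and 0.00919 with an estimated correlation). ATOH1, the transcription factor of the secretory lineage, fell by 1.27 ± 0.17 and the mucin MUC13 by 0.44 ± 0.06. Tight junction genes had 1 of 19 higher and 5 lower, 1 and 6 adjusted over the list alone (camera adjusted p = 0.00877 and 0.0152 with an estimated correlation), with CLDN2 at -0.46 ± 0.05. Of 6 glucose-responsive MondoA targets TXNIP (-1.39 ± 0.09) and ARRDC4 (-0.79 ± 0.11), both arrestin-domain proteins, fell and KLF10 (0.28 ± 0.06) rose, 2 lower and 1 higher also adjusted over the list alone (camera adjusted p = 0.00233 and 0.0408 with an estimated correlation). Stem cell and Wnt targets had 6 of 16 lower, 8 adjusted over the list alone, with SOX4 at -0.75 ± 0.07 (camera adjusted p = 1.77e-05 but adjusted p = 0.0591 with an estimated correlation). Other named falls were ADH1C (-1.82), BDNF (-1.75), SLC14A1 (-1.57), SLC3A1 (-1.56), ZNF671 (-1.40), MT-ATP8 (-1.56) and 7SK (-1.60). The rises of RN7SL2 (4.13 ± 1.33, edgeR adjusted p = 0.0281) and RN7SL1 (3.57 ± 1.04, edgeR adjusted p = 0.0151) follow the batch that RN7SL2 defines, and under a term for that batch RN7SL2 had a log2 fold change of -0.11. Not every call held without 1 library: lost, with the highest edgeR adjusted p, were RN7SL2 0.107 (vehicle 1, 2 or 3, high 2), RN7SL1 0.129 (vehicle 2 or 3, high 2) and 7SK 0.156 (vehicle 1, 2 or 3, high 1 or 3) (high against vehicle).

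**Figure D4:**
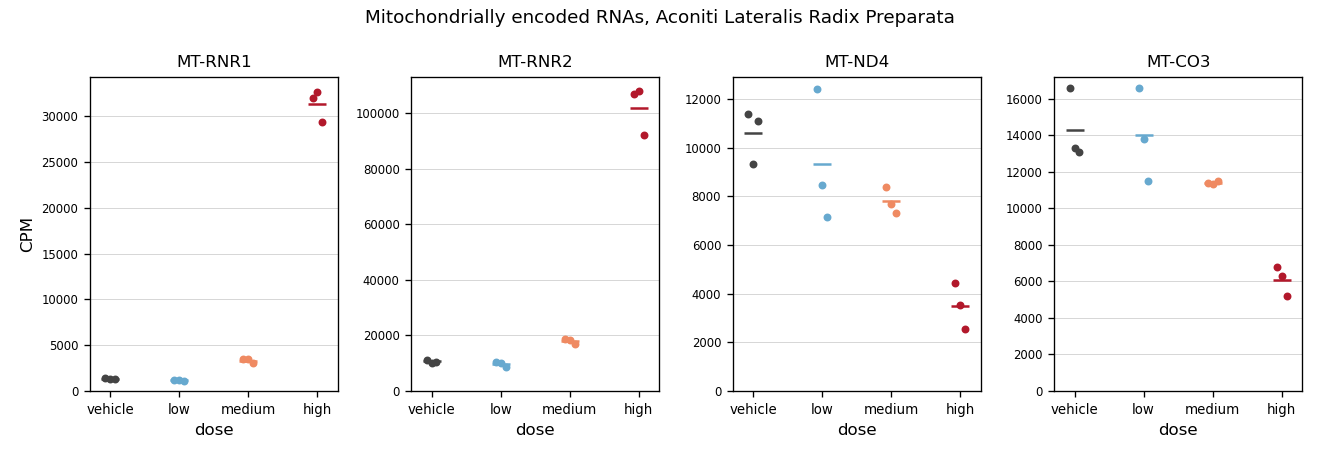
CPM of MT-RNR1, MT-RNR2, MT-ND4 and MT-CO3 in each library (points) with group means (bars) for vehicle and aconite at the low, medium and high dose, 3 libraries each. The 2 ribosomal RNAs rise from the low to the high dose, and MT-ND4 and MT-CO3 are lowest at the high dose.

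Against its own low dose, aconite at the high dose raised 951 genes and lowered 824. MT-RNR1 (4.78 ± 0.12), CYP1A1 (4.69 ± 0.17), MT-RNR2 (3.40 ± 0.10), CHAC1 (2.83 ± 0.15) and ADM2 (2.13 ± 0.19) led the rises. ADH1C (-2.07 ± 0.24), BDNF (-1.44 ± 0.20), MT-ND4 (-1.41 ± 0.16), SLC3A1 (-1.38 ± 0.23) and the interferon-induced OAS2 (-1.34 ± 0.31) led the falls. ATF4 targets had 20 of 23 higher, 21 adjusted over the list alone (camera adjusted p = 1.55e-106 and 4.86e-16 with an estimated correlation), and NRF2 targets 21 of 22, all 22 adjusted over the list alone (camera adjusted p = 1.06e-61 and 2.93e-11 with an estimated correlation). The count was 2946, 1253 and 2666 without aconite high 1, 2 and 3 and 1170 and 1072 without low 1 and 2. Against vehicle the medium dose raised 388 and lowered 352 genes and the low dose 115 and 146. These counts were 382 and 81 without vehicle 1, 473 and 135 without vehicle 2, 382 and 420 without medium 1 and 3, and 148, 107 and 79 without low 1, 2 and 3 in edgeR. A batch term, estimated within set 5 alone, gave 1919, 397 and 65 from high to low dose. Without the term 1680, 327 and 58 of these were also called. The term ended the calls of RN7SL1 and 7SK at the high dose. Fitted with vehicle alone, the high dose gave 181 genes and the low dose 84 in edgeR, and the 2 groups of high against low alone gave 94. At the high dose the fit without the 4 deviating libraries gave 2937, of which 1712 were also called with all libraries. Leaving out 1 library ended the calls of OAS2 0.076 (low 2), each with its highest edgeR adjusted p (high against low).

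Yijung-tang at the high dose raised UGT1A6, a glucuronidation enzyme, by 0.60 ± 0.09 (edgeR adjusted p = 9.9e-05), AKR1C2 by 0.75 ± 0.12 (to 17.3 ± 0.24 CPM from 10.3 ± 0.787, edgeR adjusted p = 0.000405) and CYP1B1 by 0.49 ± 0.09. CYP1A1 had a log2 fold change of 1.74 ± 0.48 that did not pass (edgeR adjusted p = 0.0595). In all 105 genes rose and 77 fell. The largest rises were of CYP2D6 (0.91 ± 0.18), CCDC78 (0.89), SEC31B (0.83), LY6G5B (0.80), the DNA glycosylase NEIL1 (0.77), RTEL1-TNFRSF6B (0.72) and NHERF4 (0.71). Falls were led by the keratin KRT17 (-0.84 ± 0.19), DOK7 (-0.53), SH3BGRL3 (-0.52), DHRS2 (-0.50), ANKRD12 (-0.49), MT-RNR1 (-0.47), C7orf50 (-0.45) and CDK2AP2 (-0.43). Of these, LY6G5B, ANKRD12, CCDC78 and RTEL1-TNFRSF6B were called in 15, 12, 11 and 10 of the 18 comparisons with the shared vehicle libraries and in 0 of those of high with low dose in edgeR. Aryl hydrocarbon receptor targets had 4 of 8 higher, 6 adjusted over the list alone (camera adjusted p = 1.4e-10 and 7.19e-05 with an estimated correlation). NRF2 targets had 5 of 22 higher, 10 adjusted over the list alone (camera adjusted p = 7.93e-09 and 0.00618 with an estimated correlation), with HMOX1 (0.31) and NQO1 (0.20) not passing. Of 7 metallothionein and metal response genes 0 passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.000349 and 0.0247 with an estimated correlation), MT1E at -0.49 ± 0.13. Without 1 library some calls of high against vehicle were lost, here with the highest edgeR adjusted p and the libraries: KRT17 0.098 (vehicle 1, high 2), SEC31B 0.0875 (vehicle 1, high 1 or 3) and RTEL1-TNFRSF6B 0.0881 (vehicle 1, high 2 or 3). Also lost were DOK7 0.212 (vehicle 1 or 3, high 1, 2 or 3), SH3BGRL3 0.292 (vehicle 1 or 2, high 1 or 3) and ANKRD12 0.0779 (vehicle 1, high 1). Further losses were MT-RNR1 0.143 (vehicle 1, high 3), C7orf50 0.343 (vehicle 1, high 1 or 3) and CDK2AP2 0.342 (vehicle 1, high 3).

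The dose effect of Yijung-tang was small, with 11 genes higher and 3 lower in high than in low. AKR1C2 (0.78 ± 0.13), the tubulin TUBA4A (0.51 ± 0.07, edgeR adjusted p = 0.000113), UGT1A6 (0.51 ± 0.09) and AKR1B10 (0.48 ± 0.09) rose, as did MT-ATP8 (1.33 ± 0.28), and C3orf52 (-0.33 ± 0.07) fell. Of 22 NRF2 targets 2 rose, 15 adjusted over the list alone (camera adjusted p = 4.67e-27 and 1.07e-06 with an estimated correlation). Without vehicle 1, 2 and 3 the counts against vehicle were 61, 107 and 235 at the high dose, 13, 93 and 518 at the medium dose and 18, 158 and 534 at the low dose. Without replicates 1, 2 and 3 of the extract they were 70, 113 and 64, then 33, 124 and 44, then 117, 40 and 23. The high-against-low comparison gave 7, 29 and 4 without high 1, 2 and 3 and 4 without low 2 or 3. The batch term, estimated within set 5 alone, gave 304, 757 and 567 genes. Without the term 124, 222 and 169 of these were also called. The compared groups alone gave 68, 47 and 78, and 73 for high against low. Without 1 library some calls of high against low were lost, here with the highest edgeR adjusted p and the libraries: MT-ATP8 0.704 (low 1, 2 or 3, high 1 or 3), UGT1A6 0.0979 (low 2 or 3, high 3) and AKR1B10 0.103 (low 2 or 3, high 3). Also lost was C3orf52 0.987 (low 1, 2 or 3, high 1 or 3).

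At every dose of Banhasasim-tang, chemokine genes were higher than in vehicle. CXCL1 reached 37.8 ± 5.52 CPM at the high dose from 1.69 ± 0.298 in vehicle, a log2 fold change of 4.51 ± 0.15 (edgeR adjusted p = 1.01e-27), with 4.41 at the medium and 4.10 at the low dose. CXCL8, the neutrophil chemokine interleukin-8 (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand), rose by 2.94 ± 0.18, 2.81 and 2.66 in the same order. The protease inhibitor PI3 (2.66 ± 0.15), complement factor CFB (1.28 ± 0.16), BIRC3 (1.10 ± 0.12), ICAM1 (0.92 ± 0.11) and TNFAIP3 (0.85 ± 0.21) rose at the high dose. Of 16 NF-kB and chemokine genes 12 rose, 0 fell and 4 did not pass, with 13 adjusted over the list alone (camera adjusted p = 1.86e-103 and 2.67e-21 with an estimated correlation). At the medium and at the low dose 11 of the 16 rose. Mitochondrially encoded mRNAs, a measure of RNA quality, had a median of -0.24 at the high dose with 0 of 13 past edgeR's test (camera adjusted p = 0.0051, but adjusted p = 0.49 with an estimated correlation). CXCL5, which had 0 counts in vehicle, is given no fold. Not every call held without 1 library: lost, with the highest edgeR adjusted p, were TNFAIP3 0.147 (vehicle 1 or 3, high 1 or 3) (high against vehicle).

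**Figure D5:**
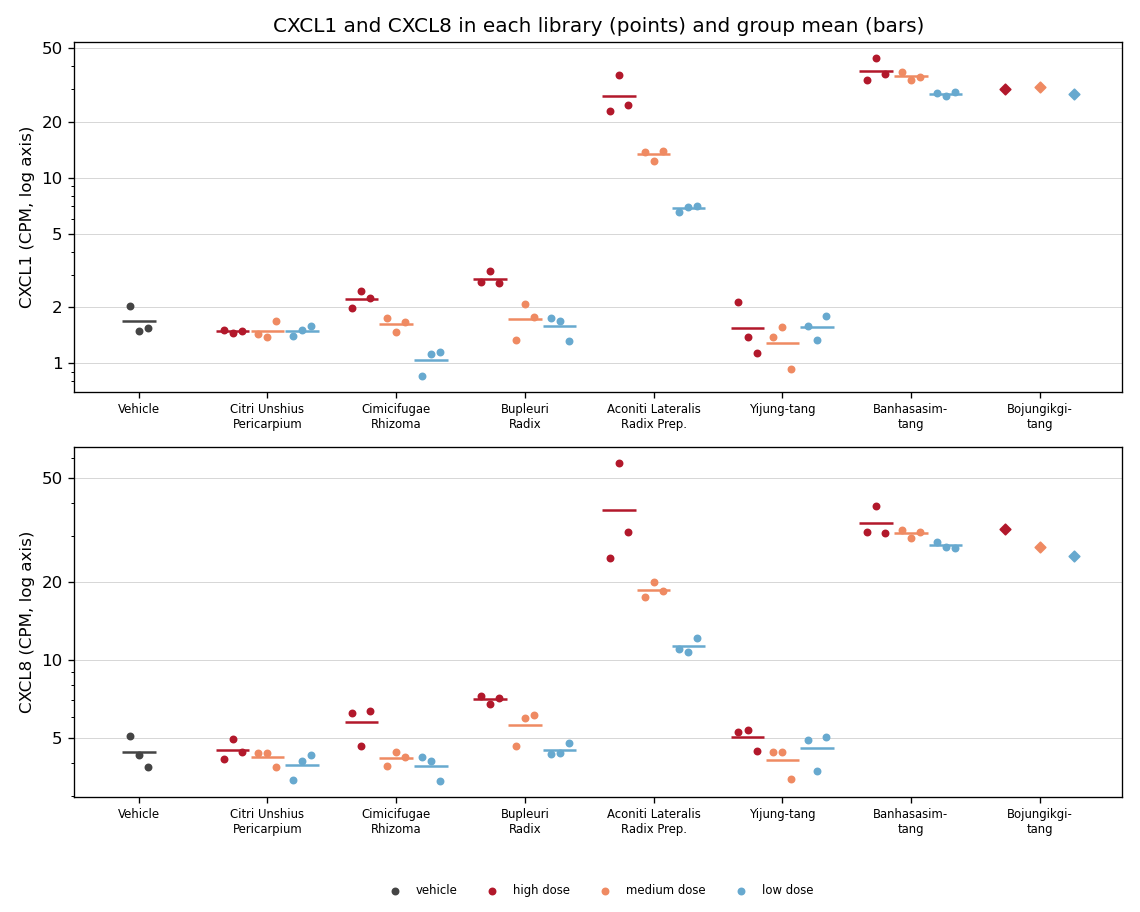
CPM (log axis) of CXCL1 and CXCL8 in each library (points, diamonds for Bojungikgi-tang) with group means (bars). CXCL1 lies near 1.69 CPM in vehicle, at 37.8 in Banhasasim-tang at the high dose and between 28.4 and 30.8 in the 3 Bojungikgi-tang libraries.

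In total the high dose of Banhasasim-tang raised 130 genes and lowered 66, in all 196 against 14 with only the compared groups in the fit. CCDC78 (0.93) was among the largest rises, and BCYRN1 (-0.97 ± 0.24), the sulfotransferase CHST3 (-0.55), CABP4 (-0.52), FAM83E (-0.52), the purinergic receptor P2RX4 (-0.50), NPIPB4 (-0.48), SLC14A1 (-0.48) and ANKRD12 (-0.46) led the falls. CCDC78 and ANKRD12 were called in 11 and 12 of the 18 comparisons with the shared vehicle libraries and in 0 of those of high with low dose in edgeR. Aryl hydrocarbon receptor targets had 3 of 8 higher, 6 adjusted over the list alone (camera adjusted p = 1.32e-07 and 0.000981 with an estimated correlation), CYP1B1 (0.37) among them and CYP1A1 not passing (0.907 ± 0.308 CPM against 0.294 ± 0.158). NRF2 targets had 5 of 22 higher, 9 adjusted over the list alone (camera adjusted p = 6.89e-07 and 0.017 with an estimated correlation), AKR1C3 (0.66 ± 0.15) among them, while HMOX1 (0.03) and NQO1 (0.26) did not pass. High against low dose changed 36 genes, 14 up and 22 down: AKR1C2 (0.77), AKR1C3 (0.69), PI3 (0.67), AKR1C1 (0.65) and ALDH3A1 (0.58) rose and AMOT (-0.75), SPRY3 (-0.68), ZNF704 (-0.60), SYTL2 (-0.58) and CHST3 (-0.54) fell. Of the 16 NF-kB and chemokine genes 0 passed there in edgeR and 2 did adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00269 and 0.0132 with an estimated correlation). Without 1 library some calls of high against vehicle were lost, here with the highest edgeR adjusted p and the libraries: BCYRN1 0.267 (vehicle 1 or 2, high 1 or 3), AKR1C3 0.212 (vehicle 2 or 3, high 2) and CHST3 0.0668 (vehicle 2, high 2). Also lost were CABP4 0.0925 (vehicle 1 or 2, high 1 or 2), FAM83E 0.163 (vehicle 1 or 2, high 1 or 3) and P2RX4 0.261 (vehicle 1, 2 or 3, high 1). Further losses were NPIPB4 0.129 (vehicle 2, high 2), ANKRD12 0.108 (vehicle 1) and CYP1B1 0.171 (vehicle 1 or 2, high 1 or 3). Without 1 library some calls of high against low were lost, here with the highest edgeR adjusted p and the libraries: AKR1C2 0.182 (low 2, high 2), AMOT 0.629 (low 1, 2 or 3, high 2) and AKR1C3 1 (low 1, 2 or 3, high 2). Also lost were SPRY3 0.182 (low 2, high 2), PI3 0.908 (low 2 or 3, high 2) and AKR1C1 0.789 (low 1, 2 or 3, high 2). Further losses were ZNF704 0.629 (low 1 or 2, high 2), ALDH3A1 0.182 (high 2) and SYTL2 0.277 (low 2, high 2). The last was CHST3 0.908 (low 1, 2 or 3, high 2).

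Counts for Banhasasim-tang rested on single libraries. Against vehicle they were 95, 95 and 93 from high to low dose without vehicle 1, 72, 288 and 276 without vehicle 2, and at the medium and low dose 842 and 863 without vehicle 3. Without Banhasasim-tang high 2, the library with short transcripts and ribosomal protein mRNAs high, the high dose gave 361 genes; the medium dose gave 184, 241 and 163 and the low dose 177, 138 and 247 without replicates 1, 2 and 3. High against low gave 785, 0 and 2930 without high 1, 2 and 3 and 11, 1 and 11 without low 1, 2 and 3. A batch term, estimated within set 5 alone, gave 144, 913 and 927 genes from high to low dose. Without the term 84, 368 and 381 of these were also called. At the high dose it ended the calls of TNFAIP3, CABP4, FAM83E, NPIPB4, SLC14A1, ANKRD12, CYP1B1 and AKR1C3. The compared groups alone gave 196 and 123 at the medium and low dose, and 0 for high against low. Without the 4 deviating libraries the high dose gave 294 genes, 126 of them also called with all libraries, and high against low 10, 7 of them also called with all.

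Bojungikgi-tang had 1 library per dose, so its differences have no replicate check. CXCL1 stood at 30.2, 30.8 and 28.4 CPM from high to low dose against 1.7 ± 0.304 in vehicle (n = 3), log2 ratios of 3.53, 3.56 and 3.44, and CXCL8 at 31.8, 27.3 and 25.1 CPM against 4.45 ± 0.634. The protease inhibitor PI3 stood at 20.4, 18.5 and 19.5 CPM against 3.93, and CCL20 and CXCL3 had log2 ratios of 2.60 and 1.71 at the high dose. RN7SL2 (2.53) and RN7SL1 (1.61) were also among the largest rises, and BCYRN1 (-1.10), MOGAT3 (-0.83), PRR36 (-0.78), the ribosomal stalk protein RPLP1 (-0.74) and ROMO1 (-0.72) the largest falls. The NF-kB and chemokine list had medians of 0.40, 0.58 and 0.44 from high to low dose, at percentile 100 of 10000 random lists in each library. In the same libraries the ribosomal protein list had medians of -0.18, -0.23 and -0.11, all at percentile 0, and mitochondrially encoded mRNAs -0.35, -0.18 and -0.08, at percentiles 0, 1.4 and 3.3. The aryl hydrocarbon receptor list had a median of 0.43 at the high dose, also at percentile 100, and 0.01 at the low dose, at percentile 62. CYP1A1 stood at 1.36, 0.307 and 0.381 CPM from high to low dose against 0.296 ± 0.159 in vehicle. Its log2 ratios of CPM + 1 were 0.86, 0.01 and 0.09, and the added 1 makes them small at such levels. HMOX1 had a log2 ratio of -0.26 at the high dose. It lay below all vehicle libraries in all 3 (7.72, 7.29 and 7.85 CPM against 9.44 ± 0.759), whereas NQO1 (0.09) did not lie beyond them. Of 10709 genes, all 3 libraries lay above all vehicle libraries for 1352 and below for 1643, where chance gives 5% each way, and the libraries form a set of their own.

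Extracts of the same library set were then compared at the high dose. Cimicifuga exceeded citrus peel in 101 genes and lay below it in 40. Levels in citrus peel relative to cimicifuga were -1.58 ± 0.28 for CYP1A1, -1.10 ± 0.11 for AKR1C2, -1.10 ± 0.13 for AKR1C1, -0.98 ± 0.12 for ABCG1 and -0.95 ± 0.08 for ALDH3A1. Levels were higher for DPYSL3 (1.07), DPH6 (0.78), the pyrimidine catabolic enzyme DPYD (0.74), RASL11A (0.68) and SLC14A1 (0.61). Bupleurum relative to aconite was lower in 955 genes, including CYP1A1 (-4.72 ± 0.17), MT-RNR1 (-4.59 ± 0.12), CXCL1 (-3.25 ± 0.13), MT-RNR2 (-3.18 ± 0.10) and CHAC1 (-2.76 ± 0.14). It was higher in 642, including ADH1C (1.70), TXNIP (1.56), MT-ND4 (9930 ± 1130 against 3500 ± 944 CPM), the Notch ligand DLL4 (1.46) and WWTR1 (1.34). Yijung-tang relative to Banhasasim-tang was lower in 45 genes, including CXCL1 (-4.56 ± 0.16), PI3 (-2.86 ± 0.16), CXCL8 (-2.72 ± 0.18), CFB (-1.78 ± 0.18) and ICAM1 (-1.02 ± 0.11). It was higher in 9, including CHST3 (0.51), SPRY3 (0.51), FAM131B (0.46), UGT1A6 (0.40) and TAF15 (0.38). The edgeR counts of 141, 1597 and 54 became, without replicates 1, 2 and 3 of the first extract, 78, 82 and 83, then 876 and 923 (replicates 1 and 2), then 35, 85 and 33. Without those of the second they became 73, 80 and 87, then 3041, 926 and 2685, then 99 and 455 (replicates 1 and 3). For citrus peel against cimicifuga the call of DPYSL3 was lost without cimicifuga high 2 (edgeR adjusted p = 0.109). For Yijung-tang against Banhasasim-tang calls were lost without 1 library, here with the highest edgeR adjusted p and the libraries: CHST3 0.577 (Banhasasim-tang 2, Yijung-tang 1 or 3) and SPRY3 0.514 (Banhasasim-tang 2, Yijung-tang 1 or 3). Also lost were FAM131B 0.18 (Banhasasim-tang 1 or 2, Yijung-tang 1 or 3), UGT1A6 0.249 (Banhasasim-tang 2 or 3, Yijung-tang 1 or 3) and TAF15 0.0669 (Banhasasim-tang 2).

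Calls overlapped between extracts at the high dose against the shared vehicle libraries. Bupleurum and aconite shared 93 higher and 100 lower genes, where independent lists of their sizes share 10.1 and 8.98. Cimicifuga and bupleurum shared 58 and 24 (0.92 and 0.63 if independent), and aconite and Banhasasim-tang 92 and 46 (11 and 4.74). Part of the excess may come from the shared controls, whose 3 libraries are too few to be parted into groups of 2. Simulated unchanged groups against 3 vehicle libraries, themselves simulated, had at most 2 calls each. That is too few to show what overlap shared controls alone would bring. The simulation also holds no deviating library and no difference between sets, so it does not describe the real vehicle libraries. Fold changes against vehicle correlated across genes with a median r of 0.501 over the 15 pairs, close to the 0.524 of the simulation. The median covariance was 0.0197 against a simulated median of 0.0125, a difference between the medians of 0.0072. Changes from low to high dose, which share no library between extracts, correlated across 12177 genes with a median r of 0.229, from 0.073 for bupleurum and Banhasasim-tang to 0.426 for aconite and Banhasasim-tang; genes are not independent replicates. The high-dose groups of this last pair hold the deviating libraries aconite high 2 and Banhasasim-tang high 2, which both had short transcripts and ribosomal protein mRNAs high.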

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

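The tests of the mitochondrial and chemokine patterns, and the separate tests of sets 6 and 7 for the low-dose calls, were chosen after the results they examine were seen; the splits of the samples, the pooled batch test and the low-dose test were set before.

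The dose effect differed between extracts of the same library set. For 17 genes the change from low to high dose differed between citrus peel and cimicifuga in an edgeR interaction test. With its sign kept, the log2 change was higher in citrus peel for 4 and in cimicifuga for 13. A gene lowered by cimicifuga and unchanged by citrus peel counts as higher in citrus peel. These numbers therefore do not rank the size of the effects. ALDH3A1 differed by -0.89 on the log2 scale (edgeR adjusted p = 1.34e-05; 0.28 in citrus peel, 1.17 in cimicifuga), HMOX1 by -0.92, AKR1C2 by -1.16, GCLM by -0.66 and the autophagy receptor SQSTM1 by -0.59. Between bupleurum and aconite 287 genes differed. With its sign kept, the log2 change was higher in bupleurum for 126, genes that fell in aconite alone included, and in aconite for 161. MT-RNR1 differed by -4.74 (edgeR adjusted p = 1.04e-27), MT-RNR2 by -3.43, CHAC1 by -2.77, ASNS by -2.02, DDIT4 by -1.95 and PSAT1 by -1.35. Between Yijung-tang and Banhasasim-tang edgeR found 0 such genes, the smallest adjusted p being 0.319.

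Bojungikgi-tang, which enters no replicated comparison, showed a signal above the vehicle libraries. CXCL1 had a log2 ratio of 3.53 to the vehicle mean at the high dose, and 14 of 23 NF-kB and chemokine genes lay above all vehicle libraries in all 3 of its libraries, with 1 below. The 14 include genes near 0 CPM, such as TNF (0.286, 0.0768 and 0.0545 CPM from high to low dose) and LTB (0.358, 0.0768 and 0.327). Of 10709 genes with a mean of at least 5 CPM, 1352 lay above and 1643 below all vehicle libraries in the same way. These libraries form set 8 by themselves.

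Mitochondrial ribosomal RNA rose with aconite while mitochondrial mRNAs fell. A general carry-over of RNA without poly(A) tails would also raise other such RNAs. For 38 of them the median from low to high dose was -0.29 (SD 0.51), with 0 higher and 6 lower in edgeR. These values argue against a carry-over that raised the 38 as well. Whether the 38 follow carry-over of mitochondrial ribosomal RNA was not tested, so carry-over of that RNA alone stays open. The deviating library aconite high 2 is not the cause, as MT-RNR1 had a log2 fold change of 4.74 without it against 4.78 with it. A response graded by dose had the values it needs, MT-RNR1 rising by 1.53 and MT-RNR2 by 0.89 from low to medium dose. A change in the tails or processing of mitochondrial RNA may also act here and was not tested.

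Chemokine genes were higher at every dose of Banhasasim-tang. A difference of library set 7 would raise them in Yijung-tang as well, where the list median at the low dose was 0.01 (SD 0.17) with 0 of 16 genes higher, against 0.72 and 11 higher in Banhasasim-tang. For a stimulus at its plateau over the dose range, the change from low to high dose, a median of 0.16, lay only just under the bound. That bound was set after the levels were seen. The camera test of this change, given above, passed with both correlations, so a small rise with dose is not excluded. A stimulus that came with the Banhasasim-tang samples and is unrelated to dose cannot be told apart from a plateau, because no dose without the response was measured.

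Many genes were called against vehicle at the low dose in sets 6 and 7: 128 for bupleurum, 261 for aconite, 241 for Yijung-tang and 473 for Banhasasim-tang. The RN7SL2 batch argues for neither side over all 4, with a median correlation of low-dose changes and the batch difference within set 5 of 0.008 (SD 0.17). For set 7 the correlation was -0.124 (rank correlations -0.319 and -0.333 for its 2 extracts). These values argue against this batch as the main source of the low-dose changes across genes in set 7. Both extracts share the vehicle libraries, so they are not independent checks. A batch part hidden under another difference between the sets is not excluded, as RN7SL2 itself separates set 7 from vehicle. For set 6 the correlation was 0.165 but the rank correlations were 0.036 and -0.057, so the measures part and the batch cannot be told apart from the set. An effect of the extracts at their low dose also stays open: the change from medium to high dose in the direction of the low-dose call was 0.064, -0.011, -0.033 and -0.127 in the order above (median -0.022, SD 0.079), below 0 in 3 of 4 extracts, the bound set before against it, but beyond the SD in only 1.

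Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In aconite at the high dose against vehicle 3 splits, the real one included, reached its count (2580, highest other 3322) and in Banhasasim-tang at the high dose 4 did, again with the real one (196, highest other 3026). The highest splits put replicates 1 and 3 of the extract with vehicle 3 and replicate 2 of the extract, a deviating library, with vehicle 1 and 2, which points to a structure of the samples. Citrus peel at the medium and cimicifuga at the low dose called 0 genes in all 10 splits with edgeR (1584 and 1362 genes at an unadjusted p under 0.05; 9 and 4 calls in DESeq2 for the real split). In each of the other 23 comparisons 1 split, the real one, reached its count; the highest other count was 1514 for aconite high against low (real 1775), 101 for bupleurum against aconite (1597), 18 for bupleurum at the medium dose (62), 8 for Yijung-tang against Banhasasim-tang (54), 3 for Banhasasim-tang high against low (36), 1 for aconite at the medium dose (740) and Yijung-tang high against low (14), and 0 for the others.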

How the results depend on the processing

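The batch term, the matched-batch libraries, the fit without 4 deviating libraries and the fit without mitochondrially encoded genes were chosen after seeing the data, the other alternatives before the data were examined. A group name with a dose alone means that dose against vehicle, and counts within 1.5 times the reported one are not listed. The cause was not tested where a value below differs. Fits of the compared groups alone and fits without libraries hold fewer samples. Fits of the compared groups alone also take the spread from those groups only, and some of their counts rose while others fell. Numbers of changed genes as reported were: citrus peel high 5, citrus peel medium 0, citrus peel low 1, cimicifuga high 211, cimicifuga medium 1, cimicifuga low 0, bupleurum high 244, bupleurum medium 62, bupleurum low 128, aconite high 2580, aconite medium 740, aconite low 261, Yijung-tang high 182, Yijung-tang medium 264, Yijung-tang low 241, Banhasasim-tang high 196, Banhasasim-tang medium 478, Banhasasim-tang low 473, citrus peel high against low 11, cimicifuga high against low 144, bupleurum high against low 48, aconite high against low 1775, Yijung-tang high against low 14, Banhasasim-tang high against low 36, citrus peel against cimicifuga 141, bupleurum against aconite 1597, Yijung-tang against Banhasasim-tang 54.

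Without a filter on low counts the counts became: citrus peel high 353, citrus peel medium 496, citrus peel low 364, cimicifuga high 581, cimicifuga medium 235, cimicifuga low 319, bupleurum high 784, bupleurum medium 873, bupleurum low 615, aconite medium 1142, aconite low 676, Yijung-tang high 489, Yijung-tang medium 673, Yijung-tang low 901, Banhasasim-tang high 409, Banhasasim-tang medium 976, Banhasasim-tang low 1200, citrus peel high against low 75, bupleurum high against low 107, Yijung-tang high against low 180, Banhasasim-tang high against low 1471, Yijung-tang against Banhasasim-tang 462.
In DESeq2 the counts became: citrus peel high 33, citrus peel medium 9, citrus peel low 18, cimicifuga medium 19, cimicifuga low 4, bupleurum high 369, bupleurum medium 270, Yijung-tang high 313, Yijung-tang medium 598, Yijung-tang low 551, Banhasasim-tang medium 750, Banhasasim-tang low 766, citrus peel high against low 38, bupleurum high against low 77, Yijung-tang high against low 31, Banhasasim-tang high against low 195.
With a term for the RN7SL2 batch, estimated within set 5 alone, the counts became: citrus peel high 12, citrus peel low 2, cimicifuga medium 2, bupleurum high 77, bupleurum medium 20, bupleurum low 14, aconite medium 397, aconite low 65, Yijung-tang high 304, Yijung-tang medium 757, Yijung-tang low 567, Banhasasim-tang medium 913, Banhasasim-tang low 927.
Without the 4 deviating libraries the counts became: citrus peel high 36, citrus peel medium 1, cimicifuga high 398, cimicifuga medium 5, cimicifuga low 2, bupleurum high 449, bupleurum low 199, Yijung-tang high 348, citrus peel high against low 114, cimicifuga high against low 439, bupleurum high against low 126, Yijung-tang high against low 115, Banhasasim-tang high against low 10, citrus peel against cimicifuga 405.
With libraries of matched batch the counts became: citrus peel high 1, citrus peel low 0, cimicifuga high 135. That fit left out only replicate 3 of set 5. It also moved citrus peel high against low to 2, cimicifuga high against low to 58 and citrus peel against cimicifuga to 54. Comparisons of sets 6 and 7 with vehicle are not batch matched there, and none of their libraries was left out. In this refit Yijung-tang medium moved to 125, low to 136 and high against low to 6. Banhasasim-tang low moved to 308 and high against low to 13.
With only the compared groups in the fit the counts became: citrus peel high 10, citrus peel low 0, cimicifuga high 107, bupleurum medium 5, aconite high 181, aconite low 84, Yijung-tang high 68, Yijung-tang medium 47, Yijung-tang low 78, Banhasasim-tang high 14, Banhasasim-tang medium 196, Banhasasim-tang low 123, citrus peel high against low 30, cimicifuga high against low 329, bupleurum high against low 125, aconite high against low 94, Yijung-tang high against low 73, Banhasasim-tang high against low 0, citrus peel against cimicifuga 300, bupleurum against aconite 104, Yijung-tang against Banhasasim-tang 6.
Without mitochondrially encoded genes the counts became: cimicifuga medium 2.

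Over the libraries left out in turn, where a group keeps 2 libraries, counts ran as follows: citrus peel high 0 to 5, citrus peel low 0 to 0, cimicifuga high 112 to 174, cimicifuga medium 0 to 4, cimicifuga low 0 to 1, bupleurum high 98 to 227, bupleurum medium 4 to 302, bupleurum low 26 to 67, aconite medium 382 to 746, aconite low 79 to 226, Yijung-tang high 61 to 235, Yijung-tang medium 13 to 518, Yijung-tang low 18 to 534, Banhasasim-tang high 72 to 361, Banhasasim-tang medium 95 to 842, Banhasasim-tang low 93 to 863, citrus peel high against low 2 to 10, cimicifuga high against low 72 to 100, bupleurum high against low 23 to 33, aconite high against low 1072 to 2946, Yijung-tang high against low 4 to 29, Banhasasim-tang high against low 0 to 2930, citrus peel against cimicifuga 73 to 87, bupleurum against aconite 876 to 3041, Yijung-tang against Banhasasim-tang 33 to 455. Leaving out 1 replicate number from every group at once moved counts further, to 0, 142 and 0 without replicates 1, 2 and 3 for citrus peel high, 2, 1546 and 19 for Yijung-tang medium and 1411, 3297 and 1302 for aconite high. Lists for Banhasasim-tang high ran from 5 to 10 (reported 9) and the median correlation of dose changes from 0.173 to 0.216 (reported 0.229).

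With an estimated correlation between genes, lists changed at the high dose numbered 3 for citrus peel (reported 8), 3 for bupleurum (8), 11 for aconite (18), 3 for Yijung-tang (6) and 3 for Banhasasim-tang (9). The median correlation of dose changes was 0.326 for genes of mean log2 CPM at least 4, 0.258 with Spearman and 0.192 without the deviating libraries.

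With a replicate block the counts became citrus peel high 10, citrus peel medium 3, citrus peel low 5. Bupleurum high against low, where every r of the pairing check passed its bound, gave 50 against 48. The block moved no other count of calls by more than 1.5 times.

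Of 4016 values of 671 named gene results under alternatives, 3428 kept direction and side of the threshold and 587 kept direction but no longer passed. Of these 587, 400 were in the fit of the compared groups alone, where 267 kept their call, 98 without a filter on low counts and 78 under the batch term. The 1 that reversed was RN7SL2 in aconite high, with a log2 fold change of -0.11 under the batch term, which RN7SL2 itself defines. The 4016 values do not include the fits without single libraries. In those fits 405 of the 671 called results kept every call, 266 lost it without at least 1 library and 0 changed sign.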

Other observations

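The lists and comparisons were set before the data were examined, and the genes called often against vehicle were counted after they were seen.

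Of 23 interferon response genes, 10 rose at the medium and 11 at the low dose of Banhasasim-tang against vehicle in edgeR, with medians of 0.64 in both. No list test was made for these 2 doses. MX1, an antiviral GTPase, rose by 0.80 ± 0.19 and 0.95 ± 0.19, IFI44 by 0.85 ± 0.16 and 0.89 ± 0.17, the oligoadenylate synthetase OAS1 by 0.66 ± 0.11 and 0.64 ± 0.11, and IRF9 by 0.61 ± 0.13 and 0.64 ± 0.13 (n = 3). At the high dose 0 of 23 passed in edgeR, 11 were higher adjusted over the list alone, and the median was 0.34 (camera adjusted p = 3.77e-09, but adjusted p = 0.0908 with an estimated correlation). The change between high and low dose had a median of -0.29 (camera adjusted p = 0.000706, but adjusted p = 0.319 with an estimated correlation), so a difference between the doses stays open.

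In aconite, 11 of 23 interferon response genes were lower at the high than at the low dose and 14 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 1.17e-08, but adjusted p = 0.0806 with an estimated correlation). MX1 fell by 1.07 ± 0.20, IRF9 by 0.89 ± 0.13 and OAS1 by 0.60 ± 0.11. Medians from low to high dose were also below 0 in citrus peel (-0.38), cimicifuga (-0.25), bupleurum (-0.35) and Yijung-tang (-0.31). In the 3 Bojungikgi-tang libraries the list had medians of 0.25, 0.43 and 0.75 from high to low dose.

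Of all genes, 39 were called in at least 9 of the 18 comparisons with the shared vehicle libraries, 19 higher and 20 lower, and 32 of the 39 were called in no comparison of high with low dose. LY6G5B was higher in 15 (median log2 fold change 0.61), PAN2 in 14 (0.46), and ANO9 (0.43), PGGHG (0.62) and the nuclear RNA NEAT1 (0.34) in 12 each, while ENSG00000279573 was lower in 14 (-1.76) and ANKRD12 (-0.41) and SLC16A1-AS1 (-0.61) in 12 each.

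Markers of fibroblasts, leukocytes, endothelium, hepatocytes and enteroendocrine cells had fewer than 5 tested genes per list. Median levels were 1710 CPM for LYZ, 353 for SERPINA1, 17.1 for APOH and 7.78 for CD68, and 0 for COL1A2, CD3D and ALB.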
